A study of Drosophila melanogaster with 3 samples.

How the data were processed

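The data are transcription factor ChIP-seq peak lists from whole Drosophila melanogaster embryos of mixed sex, collected 0 to 14 h after egg laying, from a transgenic line that carries CG1529 with green fluorescent protein (GFP) fused to its C terminus. There were 3 libraries, biological replicates 1, 2 and 3 in the labels, and they form a single group. Chromatin was sheared by sonication to 200 to 800 bp, per the labels. The labels conflict on what the libraries are: the antibody field names CG1529 as the target, while the free-text description of each sample calls it an input control. The deposited file listings show that the peaks of each library were called on that library's own alignment against 1 separate control alignment shared by all 3, so the libraries were treated here as CG1529-GFP ChIP libraries. That control alignment, a mock precipitation and the reads were not used here.

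The authors deposited 5 peak lists in dm6 coordinates, per the file listings: 1 list per library and 1 from the pooled libraries, each called at a relaxed threshold so that it holds peaks and background, and 1 joint list kept at a threshold of the irreproducible discovery rate (IDR), a measure of how consistently a peak ranks between replicates. This joint list is called the optimal list below. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The signal value of each peak (column 7) is the authors', as deposited, and how it was normalised to the control is not given in the sources used here, so it was used only to rank, filter or describe peaks within 1 list. The −log10 q-value of each peak (column 9) is likewise the authors', as deposited. It has a ceiling that many peaks share, so peaks were ranked by signal. No table column was left without a library.

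Each relaxed list holds 30000 rows. The optimal list holds 3921 rows, of which 3905 are distinct intervals and merge into 3758 separate regions. The 3905 are exactly the 3905 distinct pooled peaks with the highest signal. Sequencing depth in reads is unknown from peak lists. The lists do show a difference in strength: 6.81% of the peaks of replicate 1 lie at the highest q-value of their list, against 13.0% for replicate 2 and 13.9% for replicate 3, and the −log10 q-value at rank 3921 is 1.57, 3.42 and 3.92. No row was shared exactly between libraries.

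Genes, TSSs (transcription start sites) and exons came from the Ensembl release 115 annotation of the same assembly, with 18164 genes, 13945 of them protein-coding, and 23581 distinct TSS positions on chromosomes 2L, 2R, 3L, 3R, 4 and X. Every peak ended within the length of its chromosome in the reference sequence. The libraries were compared over their 3921 strongest peaks, the length of the optimal list. A peak counted as shared where the overlap covered at least 50% of each peak, and chance was taken from 100 circular shifts of a list along each chromosome. A summit was called promoter within 500 bp of a TSS. Promoter shares were set against 1000 sets of random positions on the same chromosomes (permutation test, two-sided). The weakest listed peaks are the last 3921 of each library's list by signal, less those that touch an optimal peak. Chromosome shares were compared with the share of TSSs by an exact binomial test, two-sided. A set of 24 gene lists was tested by Fisher's exact test, two-sided, against all other genes. A set of 14 motifs within 50 bp of the summit was tested against 1 window centred 300 bp away, with the side drawn at random, by an exact sign test, two-sided. Both families were adjusted by Benjamini-Hochberg. Words of 8 bases were ranked on 2L, 2R and X, and the first 10 were tested on 3L, 3R and 4 by a one-sided Fisher's exact test with Bonferroni adjustment. Signal at promoter and distal peaks was compared by a permutation test of medians with 100000 resamples, two-sided. Confidence intervals are exact (Clopper-Pearson, 95%) and cover counting error only. Neighbouring genes can share a peak, so genes in a list are not fully independent.

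The groups, tests, gene lists, motifs and the alternatives in the closing section were chosen before the data were examined, except where stated. The named peaks are the 25 optimal peaks of highest signal that were shared with the strongest peaks of all 3 libraries, each given by its nearest TSS, up to 4 members per gene list by signal, and CG1529. One member that this rule names is not reported here. Base composition, coding exons as a class of their own, the side of the TSS and gene bodies were added after the data were seen. Alternatives were a list length of 1960 or 7842 peaks, overlap of 1 bp or summits within 50 bp, TSS windows of 250 and 1000 bp, the stronger 1952 optimal peaks, the 2066 peaks of replicate 1 shared with both other libraries, protein-coding genes only, other motif windows and controls, a 50 kb window at CG1529, and leaving out each replicate. For replicate spread the mean ± SD over the 3 libraries is given.

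The methods were tested on simulated data on the real chromosomes, genes and flanks. A planted overlap of 60% was recovered as 60.6%. For gene lists, genes with a peak were drawn independently, without placing peaks. With no effect, 0.174% of gene lists were called, and a list with hits planted at 40% of its members was called in 100% of 50 runs. Genes that share a peak were not simulated, so the rate of false calls does not cover them. None of the 14 motifs was called between left and right flanks (0 calls), and a word planted in 9.12% of windows was found in 9.27%. For gene bodies, 3.48% of lists were called with random peaks placed uniformly, and a planted list was called in 100% of 20 runs. In both list tests the planted list was the 48 proteasome genes, and for gene bodies most of them were given a peak. These runs do not show what would be found in shorter lists or with a smaller excess. Analyses used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.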

Results

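The study mapped where the protein encoded by CG1529, a gene on the X chromosome predicted to encode a zinc finger protein, sits on chromatin in Drosophila embryos. It holds 3 replicate libraries of GFP-tagged CG1529 from whole embryos of 0 to 14 h, with no second condition, so the comparisons are between replicates, between peaks and chance, and between classes of peaks. One label calls these libraries input controls and another names CG1529 as the precipitated target. All coordinates are dm6.

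The strongest peaks were shared by all 3 libraries and lay at a mixture of promoters and introns. The highest signal in the optimal list, 3380.1, was at 3R:16309158-16309868, an intergenic site 3789 bp downstream of the nearest TSS, that of Zip89B, a zinc transporter gene. It ranked 3, 1 and 1 in replicates 1, 2 and 3. The next was at 2R:22514104-22514504 (signal 3098), 207 bp upstream of a TSS of px, which acts in wing vein patterning. The peak at 2L:480884-481302 (signal 2914) lay in an intron of ush, a GATA cofactor gene, 1391 bp upstream of cbt, a zinc finger transcription factor gene. Of the 25 named peaks, 14 were at promoters, 7 in introns, 3 intergenic and 1 in a noncoding exon, with signals from 1824 to 3380.1, and their lowest rank in any library was 42.

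The promoter shared by Chro, which encodes an interband chromodomain protein, and Ssl1, a TFIIH subunit gene, held a peak at 3L:22878708-22879102 (signal 2183), 82 bp from the Chro TSS. A peak of signal 1979.99 lay 461 bp upstream of a TSS of ph-p, a Polycomb group gene, at X:2137146-2137573. An intron of Trl, which encodes GAGA factor, held one of signal 1976 at 3L:14759316-14759730, and an intron of HmgZ, an HMG-box gene, one of 1827 at 2R:21703177-21703681. PNPase, which encodes a polynucleotide phosphorylase, had a peak 74 bp downstream of its TSS (3R:31404480-31404843, signal 2017), mRpS23 shared one with CenG1A (2L:13835301-13835639, signal 1909), and mRpS10 shared one with Art3 (3R:15229351-15229720, 1890.5). The promoters of Ugalt (X:2703685-2704093, 2694), CG14100 (3L:19590421-19590817, 2660.1), heix with CG17328 (2L:16299309-16299981, 2429.8), CG1888 (2157), CG18549 (2144), lncRNA:CR31840 (2111), Tina-1 (1950.6) and Fkbp14 (1923) completed the promoter sites. Introns of CG11050 (2734), CG9663 (1976), Lk6 (1865) and CG32772 (1824), intergenic sites nearest CG13323 (2780.3, 11923 bp away) and CG31668 (1904), and an exon of lncRNA:Vinr nearest lncRNA:CR44619 (2048) made up the rest.

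The replicates shared most of their strong peaks. Between pairs of libraries, 66.5% ± 3.19 (SD, n = 3 pairs) of the 3921 strongest peaks were shared, from 62.8% for replicates 1 and 2 to 68.7% for replicates 2 and 3. Circular shifts gave 0.953%, and p = 0.0099 for each pair by permutation, the smallest 100 shifts can give. Among the strongest 100 peaks 81.0% ± 3.00 (SD, n = 3 pairs) were shared, and among the strongest 15000, which include background, 52.6% ± 6.69 (SD, n = 3 pairs).

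**Figure D1:**
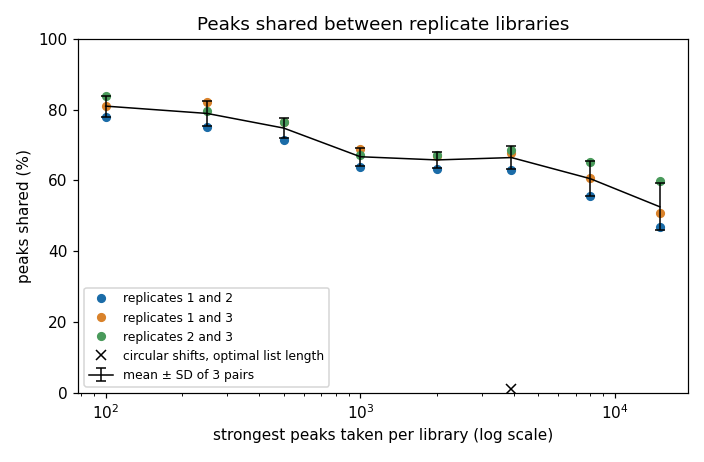
Share of peaks (%) common to each pair of libraries against the number of strongest peaks taken per library (log scale). Points are pairs, the line with bars is the mean ± SD of 3 pairs, and the cross is the share under circular shifts, 0.953%. The mean falls from 81.0% at 100 peaks to 52.6% at 15000.

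Of the 3905 optimal peaks, 1776 (45.5%, exact 95% interval 43.9 to 47.1) overlapped a strongest peak in all 3 libraries, 1127 (28.9%) in 2, 571 (14.6%) in 1 and 431 (11.0%) in 0. The optimal list was made from these same libraries, so overlap with them is built in. By any overlap with the whole relaxed lists, 3710 of the 3905 were present in all 3. Support followed signal when any overlap counted: 98.8% of the strongest 781 optimal peaks had a strongest peak in all 3 libraries, and 10.8% of the weakest 781. The share with 50% overlap was lower, 71.2%, for those strongest 781 peaks, whose median width was 285 bp against 436 bp for the weakest. Over all optimal peaks it was 22.3% when 1960 peaks per library were taken and 69.3% with 7842.

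CG1529-GFP peaks lay at promoters about 3 times as often as random positions. Summits within 500 bp of a TSS were 1627 of 3905 (41.7%, exact interval 40.1 to 43.2) against 13.6% of random positions, a ratio of 3.07 (permutation p = 0.001, the smallest 1000 sets can give). The libraries gave 38.6%, 46.4% and 43.8%, a mean of 42.9% ± 3.95 (SD, n = 3), and the weakest listed peaks 17.9%. Most promoter summits, 1256 of 1627 (77.2%, exact interval 75.1 to 79.2), were upstream of the nearest TSS, with a median position of 121 bp upstream. The libraries gave 75.0% ± 5.79 upstream (SD, n = 3). The median distance of all optimal summits to a TSS was 855 bp, 503 lay within 100 bp and 680 (17.4%) beyond 5000 bp.

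Away from promoters the peaks lay in introns and between genes and were nearly absent from coding exons. Of the 2278 summits beyond 500 bp of a TSS, 1592 were in introns and 584 intergenic. As shares of all summits, promoters included, introns held 40.8% against 39.5% of random positions, and intergenic sequence 14.96% against 27.7%. Promoters took 41.7% of summits but 13.6% of random positions, so these shares do not compare the sites away from promoters alone. Coding exons beyond 500 bp of a TSS held 7 summits (0.179%, exact interval 0.0721 to 0.369), against 13.6% of random positions and 7.43% of the weakest listed peaks. In the libraries the share was 0.230% ± 0.0442 (SD, n = 3). The 3′ UTRs held 0.691% against 4.34% at random, and annotated transposons 8 summits (0.205%) against 5.88% at random and 0.978% of the weakest peaks. Whether peaks can be called in transposons was not tested.

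**Figure D2:**
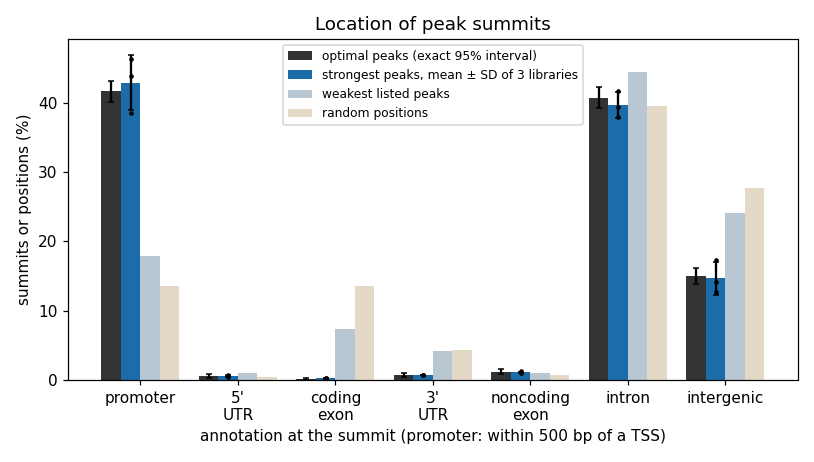
Share of summits or positions (%) by annotation. Black bars are the optimal peaks with exact 95% intervals, blue bars the mean ± SD of the strongest peaks of 3 libraries with each library as a point, and pale bars the weakest listed peaks and random positions. Promoters hold 41.7% of optimal summits against 13.6% of random positions, and coding exons 0.179% against 13.6%.

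Chromosome 4, which is largely heterochromatic, held 12 optimal peaks (0.307%), below its 0.776% of TSSs (adjusted p = 0.000488, exact binomial test), with 0.451% ± 0.0779 in the libraries (SD, n = 3). Arm 2R was below its share of TSSs (17.4% against 20.6%, adjusted p = 1.46e-06, exact binomial test) and 3L above (21.9% against 19.3%, adjusted p = 0.000124). The X held 17.7% against 16.6% of TSSs (p = 0.0501, adjusted p = 0.0752, exact binomial test), and 17.1% ± 0.647 in the libraries (SD, n = 3), so a departure was not shown. 2L and 3R did not pass either (adjusted p = 0.850 for each, exact binomial test). Against length in place of TSSs, 3L (adjusted p = 0.254), 3R (0.491) and X (0.785) did not pass, 2R was lower (18.9%, 0.0299) and 2L higher (19.3% of peaks against 17.6%, 0.0136), and chromosome 4 lower (1.01%, 3.23e-06), by the same exact test. The weakest listed peaks had 17.6% on 2R, 21.8% on 3L, 19.7% on 2L and 1.06% on 4, so the shares of 2R, 3L and 2L were much alike in weak and optimal peaks. The binomial test counts peaks as independent, while peaks were clustered (below), so its p-values are likely too small.

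Genes of cytoplasmic ribosomal proteins had a peak far more often than other genes. A summit lay within 500 bp of a TSS at 63 of 93 (67.7%, exact interval 57.3 to 77.1) against 11.1% of all other genes (adjusted p = 3.17e-36, Fisher's exact test). The libraries gave 49.5%, 68.8% and 68.8%, and the list passed in 3 of 3. Among the 2066 peaks shared by all 3 libraries the share was 30.1% (adjusted p = 2.16e-11, Fisher's exact test). Sharing needs 50% overlap, a rule that narrow peaks can miss. Among the strongest 781 optimal peaks, 71.2% had support in all 3 libraries by that rule and 98.8% by any overlap. How much of the lower share at ribosomal protein genes comes from this rule was not tested. High signals were at RpS27 (3R:25247365-25247691, 913, summit 2 bp from a TSS), RpL7 (2L:10200903-10201183, 866) and RpL34b (3R:9401191-9401452, 631). At these 63 genes 41 summits (65.1%) were upstream of the TSS, with a median position of 17 bp upstream. In all, 2076 of 18164 genes (11.4%) and 1848 protein-coding genes (13.3%) had a summit this close, and 1316 genes had one in the lists of all 3 libraries.

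Another 4 of the 24 lists were above other genes. Heat shock genes had peaks at 6 of 15 (adjusted p = 0.0118, Fisher's exact test), with Hsp27 (signal 1135), Hsp83 (868), Hsp26 (455) and Hsc70-5 (399). Genes of insulator and architectural proteins, which organise chromosome domains, had them at 7 of 19 (36.8%, adjusted p = 0.0112, exact test), with Chro (2183), Cp190 (923), Trl (467) and Dref (431). Cell cycle and replication genes had them at 9 of 32 (28.1%, adjusted p = 0.0190, exact test), with Dp (428), dpa (300.4), E2f1 (264) and Cdk1 (241), and translation factor genes at 12 of 51 (23.5%, adjusted p = 0.0282), with eIF4EHP (1121), eIF6 (1077), eEF1gamma (747) and eIF1 (594). The peaks given for Dref and eIF1 lay nearer to TSSs of ribosomal protein genes (16 against 68 bp and 60 against 321 bp) and count in that list too, and that of Cdk1 nearer to a TSS of a mitochondrial ribosomal protein gene (176 against 224 bp). The peak given for eIF4EHP lay nearer to a TSS of CG18428 (138 against 238 bp), and that of eIF6 nearer to one of asRNA:CR45928 (68 against 97 bp). By the same exact test, the insulator list (15.8%, adjusted p = 0.2003) and the cell cycle list (12.5%, adjusted p = 0.226) did not pass among the 2066 peaks shared by all 3 libraries, nor the cell cycle (9.38%, adjusted p = 0.655) and translation factor lists (15.7%, adjusted p = 0.0509) among the stronger 1952 peaks. Neither of the latter lists passed among protein-coding genes only (adjusted p = 0.0871 and 0.0947, exact test), nor translation factors at 1000 bp (adjusted p = 0.1004).

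Chemoreceptor, histone, microRNA, snoRNA and tRNA genes were below other genes within 500 bp of the annotated TSS. No odorant receptor gene (0 of 59) or gustatory receptor gene (0 of 60) had a peak (adjusted p = 0.00623 for each, Fisher's exact test). Nor did any of 111 replication-dependent histone genes (0, adjusted p = 2.30e-05, same exact test), which are repeated copies in 1 cluster. The test counts these copies as separate genes. Whether peaks can be called in repeated copies was not tested, so this 0 does not show a lack of binding. MicroRNA genes had peaks at 7 of 260 (2.69%, adjusted p = 4.20e-06), snoRNA genes at 13 of 269 (4.83%, adjusted p = 0.00132) and tRNA genes at 18 of 290 (6.21%, adjusted p = 0.0112), by the same exact test. Most genes compared, 13945 of 18164, were protein-coding, and 13.3% of protein-coding genes had a peak against 11.4% of all genes. No test was run against noncoding genes only, so these lists are not shown to be low for noncoding genes. The TSS used is the 5′ end of each annotated transcript. Whether transcription of microRNA, snoRNA and tRNA genes starts at that end was not tested, so their promoters are not shown to lack peaks. With the stronger 1952 peaks both receptor lists (adjusted p = 0.0711 for each) and tRNA genes (0.0509) missed the threshold of the exact test, and with shared peaks the receptor lists did (0.114). For snoRNA genes the direction turned with a window of 1000 bp (16.7% against 14.3%, adjusted p = 0.360, exact test). Several snoRNA peaks within 500 bp are also counted for ribosomal protein genes, among them those of RpL14, RpL28, RpL17 and RpL3.

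Developmental and other housekeeping lists did not pass in the optimal list. By library, Polycomb and trithorax group genes passed in 2 of 3, as translation factor genes did. Neural and mitochondrial ribosomal protein genes each passed in 1. Hox genes had peaks at 0 of 8, segmentation genes at 2 of 30 (nkd and bcd), neural genes at 6 of 25 (adjusted p = 0.116, Fisher's exact test), among them elav with signal 1282, muscle and mesoderm genes at 4 of 19 (sls, tin, htl and Tm1), zygotic genome activation genes at 5 of 23, Polycomb and trithorax group genes at 5 of 23 (ph-p, brm, E(z), ph-d and Psc) and ZAD zinc finger genes at 5 of 21. Germline genes had them at 3 of 23, dosage compensation genes at 0 of 7, yolk and chorion genes at 0 of 17 and snRNA genes at 4 of 32. Mitochondrial ribosomal protein genes were at 12 of 73 (16.4%, adjusted p = 0.290, exact test) and proteasome genes at 3 of 48 (6.25%, adjusted p = 0.458). Lists of this size leave wide intervals, 0 to 36.9% for Hox genes.

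**Figure D3:**
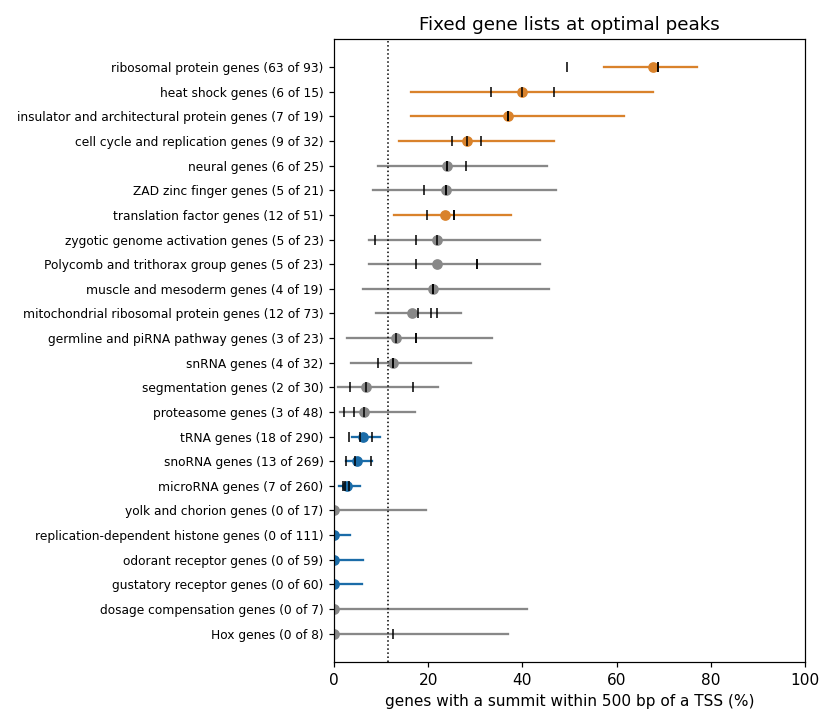
Share of each gene list (%) with an optimal summit within 500 bp of a TSS. Dots and lines are the share and its exact 95% interval, ticks the 3 libraries and the dotted line all genes, 11.4%. Orange lists passed above and blue below other genes at an adjusted p of 0.05, and ribosomal protein genes stand at 67.7%.

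The summits were rich in A and T. All 10 of the 8-base words carried over from 2L, 2R and X contained only A and T, and all 10 passed on 3L, 3R and 4, at 2.39 to 3.9 times their share in the flanks (highest adjusted p = 5.85e-05, Fisher's exact test). ATTTAAAA was within 50 bp of 6.52% of summits and in 1.74% of flank windows. When discovery was swapped to 3L, 3R and 4, 10 passed, of which 1 was the same word. Against shuffled summit windows of the same dinucleotide content, an alternative chosen after seeing the data, 10 words also passed, of which 7 held G or C and 3 did not. CACTGAGA was in 1.12% of test windows and 0.112% of shuffled ones (adjusted p = 0.00058, exact test), CACAGTGG in 0.899% and 0.0562% (0.00133) and CACTGTGC in 0.730% and 0.112% (0.0363). Their shares in flanks are not given here, so shuffled windows alone do not show that these words mark summits. The GAGA motif, below, was above shuffled windows but rarer at summits than in flanks. Mean G+C within 50 bp was 33.8% at optimal summits and 44.0% at 300 bp to either side, and 34.4% ± 0.976 against 43.9% ± 0.428 in the libraries (SD, n = 3), a measure added after the words were seen.

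**Figure D4:**
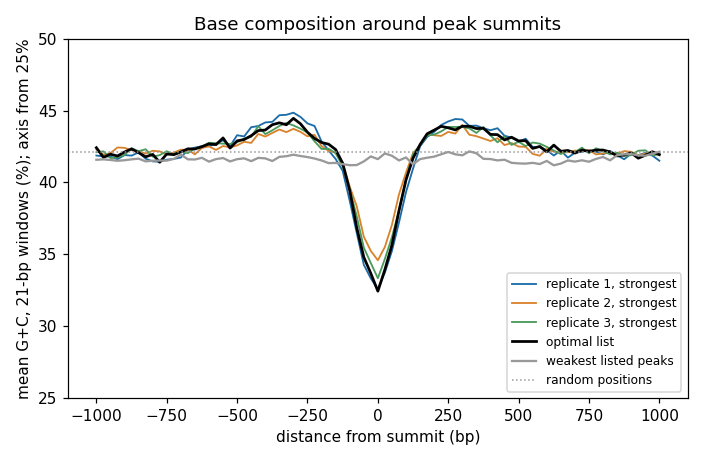
Mean G+C (%) in 21-bp windows against distance from the summit (bp), for optimal peaks, the strongest peaks of each library and the weakest listed peaks, with random positions as a dotted line. The axis starts at 25%. The strong lists drop at the summit and the weakest listed peaks stay near the random level of 42.1%.

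Of the 14 fixed motifs, 6 were more frequent at summits than in flanks and 2 less frequent. The homeodomain core TAATTA was at 9.94% of summits against 5.12% of flanks (adjusted p = 2.36e-14, exact sign test), and Ohler motif 6, a core promoter element, at 4.56% against 1.61% (adjusted p = 3.72e-13). CTCF (0.922% against 0.333%, adjusted p = 0.00491), TATA box (2.20% against 1.31%, 0.00986), Su(Hw) (0.768% against 0.307%, 0.0119) and DRE (0.768% against 0.359%, 0.0396) motifs were rarer but also higher by the exact sign test. GAGA was lower, 1.51% against 4.05% (adjusted p = 3.68e-11, exact sign test), and so was the E-box CAGCTG (3.64% against 4.87%, adjusted p = 0.0170). Against shuffled summit windows of the same dinucleotide content these directions turned for GAGA (0.359% in shuffled windows), the E-box (1.18%) and the homeodomain core (11.98%), and the TATA box did not pass. With the stronger 1952 peaks the CTCF (0.922% against 0.359%, adjusted p = 0.121), TATA box (2.25% against 1.38%, 0.133), Su(Hw) (0.820% against 0.359%, 0.168) and DRE (0.871% against 0.410%, 0.168) motifs did not pass the exact sign test. Among the 2066 peaks shared by all 3 libraries CTCF (1.02% against 0.629%, adjusted p = 0.357), DRE (0.629% against 0.387%, 0.475) and Su(Hw) (0.823% against 0.339%, 0.149) did not pass the same exact test, and the TATA box did (2.76% against 0.726%, 2.29e-06). The other 6 motifs, of BEAF-32, M1BP, Zelda, Ohler motif 7, the initiator and Bicoid, did not pass against flanks within 50 bp. Within 100 bp BEAF-32 (adjusted p = 0.0110), M1BP (0.0387), Ohler motif 7 (5.13e-05) and, as lower, the initiator (16.8% of summits, 0.0148) passed, and against shuffled windows BEAF-32 (0.000255), M1BP (0.00304), Ohler motif 7 (0.0417) and, as lower, Bicoid (2.97% against 4.71%, 0.000142), all by the exact sign test.

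Within the optimal list, promoter peaks were stronger than distal ones by a small margin. The median signal was 274 for 1627 promoter peaks and 245 for 2278 distal peaks, a log2 difference of 0.16 ± 0.03 (bootstrap SE; p = 1e-05, the smallest 100000 resamples can give, permutation test). The libraries differed: 0.28 in replicate 1 (p = 1e-05, permutation test), -0.00 in replicate 2 (p = 0.914) and 0.07 in replicate 3 (p = 0.00445), a mean of 0.12 ± 0.15 (SD, n = 3) that is smaller than its spread.

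CG1529 itself (FBgn0031144, X:21028652-21031950, minus strand) had 0 optimal peaks in its body. Within 20 kb lay 3 optimal peaks, a count above 73.1% of genes, whose median is 1. The nearest, at X:21028061-21028496 (signal 227, rank 2330, shared with 2 libraries), lay with its summit 373 bp beyond the 3′ end of the gene and 82 bp from a TSS of a neighbouring gene. Replicates 1, 2 and 3 had 2, 4 and 3 of their strongest peaks in the window. In their whole relaxed lists the counts in the window were above 43.1%, 66.8% and 70.2% of genes. The tagged transgene adds copies of this region, so peaks there may reflect copy number, which was not tested.

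**Figure D5:**
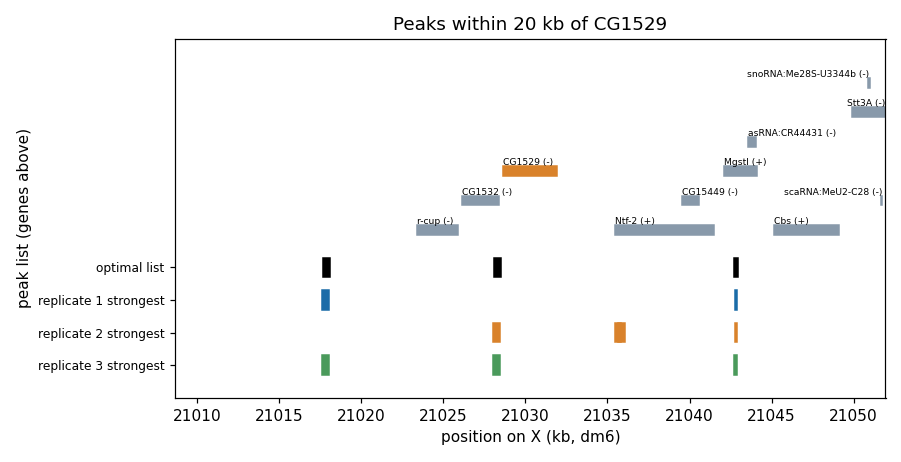
Map of X within 20 kb of CG1529 (kb, dm6), with genes and their strand above and peaks of the optimal list and the strongest 3921 peaks of each library below. The optimal list has 3 peaks there, none inside CG1529.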

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

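Several results with a test kept their direction and side of the threshold under the alternatives run for each. These results were the overlap between replicates (53.7% with summits within 50 bp to 74.8% with 1 bp), the promoter share (30.1% at 250 bp to 52.6% at 1000 bp), the X share (p from 0.0623 to 0.153, exact binomial test) and the promoter signal difference (log2 0.09 at 250 bp to 0.23 for shared peaks). The signal difference was run only with other TSS windows and shared peaks. By library, it was not found in replicate 2 (log2 -0.004, p = 0.914, permutation test). Support in all 3 libraries, given without a test, ran from 22.3% with 1960 peaks per library to 69.3% with 7842. Leaving out each replicate gave 62.8% to 68.7% for overlap, 41.2% to 45.1% for the promoter share and 16.9% to 17.5% for the X. Support in both remaining libraries was 51.0% to 57.7%. That rule is easier and cannot give less than support in all 3, so these values do not measure dependence on a replicate. Of 8-base words only 10 are carried to the test and all 10 passed in each setting, so the count cannot rise and says little. The words changed: 7 were the same with the stronger 1952 peaks, 6 at 100 bp, 1 with discovery swapped and 2 against shuffled windows, an alternative chosen after seeing the data. The number of gene lists past the threshold was 11, and 6 with the stronger 1952 peaks, 7 with peaks shared by all 3 libraries and 6 with protein-coding genes only, where fewer lists are tested. The number of motifs was 8, and 4 with 25 bp windows, 4 with the stronger peaks and 5 with shared peaks, all with fewer peaks or bases. It was 12 with windows of 100 bp and 11 against shuffled windows. At CG1529 a 50 kb window held 6 peaks.

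Single lists turned direction for snoRNA genes (16.7% at 1000 bp), and, without having passed, for neural genes (0% at 250 bp), germline genes (13.04% among coding genes), zygotic activation genes (4.35% for shared peaks) and snRNA genes (3.13% for stronger peaks). Motifs turned for GAGA (1.51%), the E-box (3.64%) and the homeodomain core (9.94%) against shuffled windows, which hold composition and remove local sequence, and, without having passed, for BEAF-32 (11.3% for shared peaks) and Zelda (0.282% at 25 bp). The cause was not tested. Depth in reads is unknown, and replicate 1 has fewer peaks at its highest q-value than the others.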

Other observations

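The tests of summit composition against weak peaks, of whether coding sequence can be called, of housekeeping genes, of peak density and of list size were chosen only after the result was seen. The gene body test and the 3 matched comparisons were added after the data were seen but written before their results. In gene bodies and 5 kb to each side, compared with 10000 random lists matched for gene length, 4 of the 24 lists were above and 4 below at an adjusted p of 0.05. Each random list drew its genes independently, at the rate of genes of like length. Listed genes that lie together can share a peak, so these p-values are likely too small. Ribosomal protein genes had a peak at 78.5% against 32.6% for matched lists and snoRNA genes at 56.5% against 29.8% (adjusted p = 0.0006 for both by permutation, from the smallest p 10000 lists can give). Some snoRNA genes share their peaks with ribosomal protein genes, so the snoRNA result is not separate evidence. Cell cycle genes stood at 68.8% against 39.8% (adjusted p = 0.00384 by permutation) and mitochondrial ribosomal protein genes at 46.6% against 29.8%. Odorant receptor genes were lower, 5.08% against 34.4%, and gustatory receptor, histone and microRNA genes too, with the limit given above for the repeated histone copies. With random peaks 3.48% of lists were called in the self-test, so some calls here are expected by chance. The clustering described next was not simulated, so that rate may be too low. Peaks were also clustered: of 1342 windows of 100 kb, 372 (27.7%) held 0 peaks, against 5.45% under a Poisson count of the same mean, and the densest, 3L:600001-700000, held 16.

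The A and T rich summits were the first pattern weighed. The weakest listed peaks changed by only -0.177 percentage points from flank to summit (mean of 3 libraries), against -10.2 for optimal peaks, which argues against a caller that places every summit in such sequence. They differed by -0.368 points from random positions, but they were selected for low signal, and fragments recovered in excess would lift a peak out of that set, so this value does not decide. Over-recovery of A and T rich fragments in all libraries stays open. As description, 1.47% of random positions at or below the median summit G+C lay in an optimal peak, against 1.06% of all. Optimal summits were -7.64 points from random positions matched for chromosome and region, which argues against region classes.

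Few summits lay in coding exons, 17 of 3905 (0.435%, exact interval 0.254 to 0.696) with promoters included. Random positions matched for chromosome and G+C lay there at 5.92%, which argues against composition alone. The weakest listed peaks lay there at 9.86%, which argues against a complete failure to call coding sequence. Unmatched random positions stood higher, at 16.7%, so a partial loss of calls in coding sequence stays open. Whether open chromatin outside coding exons accounts for the few coding summits was not tested.

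Ribosomal protein promoters were the last pattern. The upper exact limits of the proteasome and mitochondrial ribosomal protein shares reached 27.0% in the optimal list, below 33.9%, which is 50% of the ribosomal protein share. The proteasome limit was below that bound in each replicate and in shared peaks too (11.1% against 15.1% in the latter), which argues against a like call at every housekeeping gene. The mitochondrial limit was not below it in replicate 1 (28.5% against 24.7%) or in shared peaks (22.1% against 15.1%). The bound in shared peaks depends on the 50% overlap rule, which narrow peaks can miss. Translation factor genes were above other genes, at 23.5% with an upper limit of 37.5%, so a call at part of the housekeeping genes stays open. Coding genes matched for the lowest G+C within 500 bp of a TSS had a peak at 13.6%, which argues against such stretches alone. Strong transcription may raise background in any precipitation, and this stays open because transcript levels and a mock precipitation were not analysed here.

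A last hypothesis was that peaks gather in developmental gene bodies beyond their length. Of the Hox, segmentation, neural, muscle and zygotic activation lists, 0 of 5 passed. Hox genes stood at 75% against 59.5% for matched lists (adjusted p = 0.664 by permutation), muscle genes at 68.4% against 51.9% (0.280), zygotic activation genes at 52.2% against 43.5% (0.664), neural genes at 60% against 40.1% (0.118) and segmentation genes lower, at 30% against 43.8% (0.255). The prediction, written before the test, took no list passing as evidence against the hypothesis that optimal peaks gather in and within 5 kb of the bodies of developmental genes beyond their length. That was wrong, a reading made after the result was seen, because a missed threshold shows no absence and 4 of the 5 lists stood above their matched lists, so the hypothesis stays open. The size of excess that would be found was simulated only after the result was seen. With all 5 lists raised by 10, 20 or 30 percentage points, at least 1 passed in 28.2%, 76.7% and 98.8% of 1000 runs, so a small excess would often be missed.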
